A study of Caenorhabditis elegans with 4 samples.

How the data were processed

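Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where ZHP-3 sits on the genome of the nematode Caenorhabditis elegans. ZHP-3 is a RING-finger protein of the meiotic germline that loads along paired homologous chromosomes and is needed for crossovers. Per the labels, all 4 samples came from hermaphrodites of the strain fem-2(b245), which carries an allele of the sex-determination gene fem-2, grown at 20 °C. The stage label reads young adult with a germline, while the growth protocol describes cultures grown until gravid; this difference was not resolved. Per the labels' protocols, frozen worms were ground, fixed with 1% formaldehyde for 10 min and sonicated. ZHP-3 was then precipitated with 5 µg of an affinity-purified rabbit polyclonal antibody. The labels give 2 ChIP samples and 2 input samples, each numbered as replicates 1 and 2, and say nothing on whether the replicates came from separate cultures. The spread between them may therefore be technical.

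The deposited files used were 3 peak lists, 1 per ChIP replicate and 1 for the whole series, referred to here as the combined list. Per the file headers, coordinates are on the WormBase WS220 genome build. The submitters' processing notes name BWA and the ce10 build. Per the source column of the files, the authors called the replicate peaks with MACS and the combined list with MACS v2. The caller's settings, the control used and which reads entered the combined list are not given in the sources used here. The peak names of the combined list carry the series name and no replicate number, so it was not treated as an independent sample. Each deposited peak has a first and last base and a score made by the authors' peak caller, whose scale the files do not state. The lowest score was 50.04 in replicate 1, 50.02 in replicate 2 and 1.31 in the combined list. Scores were used only to rank peaks within a list. In replicate 1, 165 peaks shared the score 3100, and in replicate 2 190 peaks did, so the order among the strongest peaks is partly tied.

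The lists hold no read counts, so the sequencing depth is unknown and no interval that needs it was computed. No reads or peak lists of the input samples were analysed here, and no comparison of ChIP with input was made. No genome sequence or gene annotation on WS220 was used here. The gene table at hand is on WBcel235, another build. Peaks were therefore not assigned to genes, and the planned tests of transcription start sites and gene lists were not run.

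Values were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and drawn with matplotlib 3.10.9. The length of each chromosome was taken as the last base covered by the combined list, since the files state no lengths and the plan to take them from a reference needed one on the same build. Peaks of 2 lists were counted as overlapping from 1 bp. Regions found in both replicates are the merged intervals of overlapping peaks that hold a peak of each replicate. The chance level of overlap was set by 1000 circular shifts of a list, each chromosome by its own random offset, which keeps peak widths and spacing. Each chromosome was divided into 3 equal parts, and peaks were placed on arms (the outer parts) or in the centre (the middle part) by their midpoint. The arm to centre ratio of peak density was tested by 1000 circular shifts, two-sided, and its 95% range is that of the shifted ratios centred on the observed one. These tests treat positions within a library as the unit and say nothing on the spread between libraries. The smallest p that 1000 permutations can give is 0.001. The X share of peaks has an exact Clopper-Pearson 95% interval over peaks, which covers counting error only. Scores of paired peaks were compared by Spearman's rank correlation with a permutation of pairs within chromosomes, across peaks, which are not independent replicates. No test across the 2 replicates was run; their values are given with the SD.

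The statistics were tested on simulated, clustered lists of 6000 peaks. Of 100 simulations without an arm excess, 5% gave p under 0.05, against 84% at a simulated ratio of 1.1 and 100% at 1.2. These lists were less clustered than the data, with a mean 95% range of shifted ratios of 0.944 to 1.06. The arm test was therefore repeated on the real lists, moved by random circular shifts and thinned in the centres. Without an arm excess, 6% of 100 simulations passed for replicate 1, 2% for replicate 2 and 8% for the combined list. A share near 5% was fixed in advance here, because the lists were moved by the same kind of shifts that the test uses. These shares therefore do not check the test on the data. At a ratio of 1.1, 34%, 52% and 29% passed, and at 1.2, 87%, 99% and 89%, so a ratio near 1.1 is often missed. For lists sharing 70% of their peaks, the mean recovered share was 71.0% after taking off chance. That correction used the simulated share itself and was not applied to the data. Of 100 unrelated pairs of lists, 7% passed the overlap test.

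The design, the regions to be named and most alternatives were fixed before the data were examined. The rule for named regions took the 10 highest-scoring combined peaks that overlap a peak in both replicates, plus the highest on each chromosome. All of the latter were already among the 10, and no mitochondrial peak met the rule. Alternatives were a 50% reciprocal overlap, the higher-scoring 50% of each list and random placement of peaks as the chance level. Further ones were covered bases in place of peak numbers, the outer parts of 4 equal parts as arms, and autosomes or X alone. The others were the combined list, leaving out each replicate, and the Pearson correlation of log2 scores. Chosen after seeing the data were the lower-scoring 50% of each list, the correlation without scores of 3100 or more, the peaks of the combined list that are in neither replicate, the test of each chromosome by shifts along the joined chromosomes, and all wide regions, chromosome ends, blocks, windows and neighbour distances.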

Results

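ZHP-3 ChIP-seq of fem-2(b245) hermaphrodites gave 6537 peaks in replicate 1 and 6086 in replicate 2. The combined list of the series held 11798 peaks. Median peak width was 405 bp in replicate 1, 404 bp in replicate 2 and 318 bp in the combined list. Peaks covered 3.71 Mb, 3.35 Mb and 5.83 Mb, which is 3.70%, 3.34% and 5.80% of the 100.3 Mb of nuclear genome spanned by the lists, the last value leaving out the mitochondrial peaks. The 2 input samples entered no comparison, and the read depth behind the lists is unknown.

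The first comparison asked whether peak calls recurred between the replicates, without a comparison with input. Most did. Of the replicate 1 peaks, 4799 of 6537 (73.4%) overlapped a replicate 2 peak, against a mean of 6.41% after circular shifts (95% range 5.77% to 7.05%). Of the replicate 2 peaks, 4974 of 6086 (81.7%) overlapped a replicate 1 peak, against 6.90% by chance. Both overlaps had a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. Merging the lists gave 7484 regions, of which 4634 (61.9%) held a peak of each replicate and spanned 3.36 Mb.

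Overlap rose with the score of a peak. In the lowest score decile, 32.0% of replicate 1 peaks and 49.7% of replicate 2 peaks had a partner. In the highest decile, 98.6% and 99.8% did. Scores of the 4685 mutually paired peaks had a Spearman correlation of 0.75 across peaks (permutation p = 0.001, two-sided, the smallest possible). Replicate 1 had 1738 peaks without a partner and replicate 2 had 1112.

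**Figure D1:**
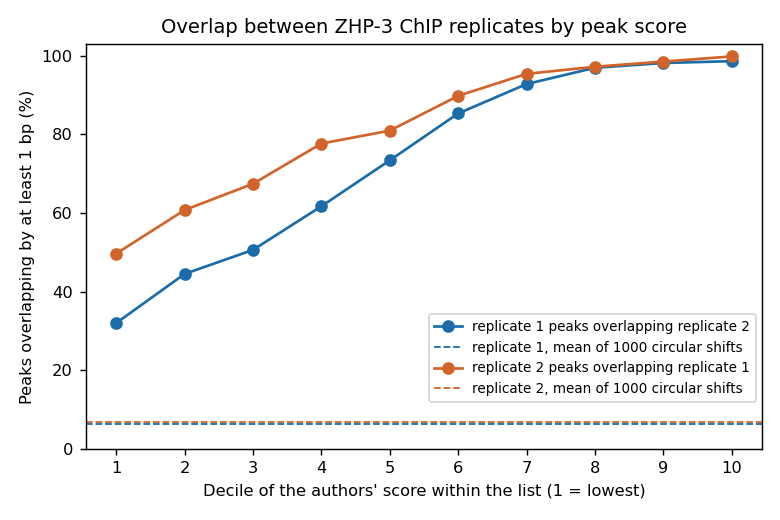
Share of peaks (%, y axis) that overlap a peak of the other replicate by at least 1 bp, in deciles of the authors' score within each list (x axis, 1 is lowest). Points are 1 decile of 1 replicate, dashed lines the mean of 1000 circular shifts; the share rises from 32.0% to 98.6% in replicate 1 and from 49.7% to 99.8% in replicate 2.

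The combined list contained nearly all replicate peaks. It was overlapped by 99.2% of replicate 1 peaks and 99.4% of replicate 2 peaks. Of its own 11798 peaks, 4445 (37.7%) overlapped a peak in both replicates. As the list covers the same ChIP experiment, this overlap is a description and not a test. Another 1456 (12.3%) overlapped replicate 1 alone and 978 (8.29%) replicate 2 alone. The remaining 4919 (41.7%) overlapped neither. Among the higher-scoring 50% of the combined list, 71.3% were in both replicates and 6.97% in neither.

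The strongest shared sites were spread over all 6 nuclear chromosomes, with 3 of the 10 on chromosome III, 3 on IV and 1 on each of I, II, V and X. All coordinates are on WS220, and no gene was assigned to them. The highest score of the combined list, 227.46, belonged to a 726 bp peak near the right end of chromosome III (13643215 to 13643940). Its replicate 1 peak scored 2621.08 and its replicate 2 peak 3100. The second was a 5399 bp peak near the right end of chromosome II (15137583 to 15142981), with a combined score of 224.57 and a score of 3100 in both replicates. This peak overlaps 1 of the wide regions described below, for which repeated sequence was not tested. Next was a 1306 bp peak on the left arm of chromosome IV (3313187 to 3314492, combined score 223.54). The site after it, with a combined score of 222.44 and 3100 in both replicates, lay on the X at 11605260 to 11606513.

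The next 6 sites had combined scores from 220.36 down to 209.22. They lay on I (10421090 to 10422511), IV (9196053 to 9197366), III (1924795 to 1925664), V (6070683 to 6072971), III (3843697 to 3846299) and IV (4727605 to 4728257). The sites on III at 1924795 and on V at 6070683 were at 3100 in both replicates. The V site lies at the left edge of a 25.4 kb block of neighbouring regions described below. Without input, such blocks cannot be told apart from reads piling on repeated sequence. Every one of the 10 sites ranked high in both replicates, with the lowest score percentile at 96.6 in replicate 1 and 95.3 in replicate 2. By midpoint, 8 of the 10 lay on arms and 2 in centres, a count that was not tested. Arms make up 2 of the 3 equal parts of each chromosome.

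Peak density was then compared between chromosomes. Chromosome III had the highest density, 77.9 ± 4.31 peaks per Mb (SD, n = 2). Chromosome I followed with 71.8 ± 5.25, IV with 67.1 ± 6.10, II with 59.6 ± 2.27 and V with 54.8 ± 1.86 peaks per Mb. The X had the lowest density, 52.1 peaks per Mb, with the same number of 924 peaks in each replicate. The order of the chromosomes was the same in both replicates. In the regions found in both replicates, III (57.4 per Mb) and I (55.0 per Mb) were again highest and the X (38.5 per Mb) lowest.

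**Figure D2:**
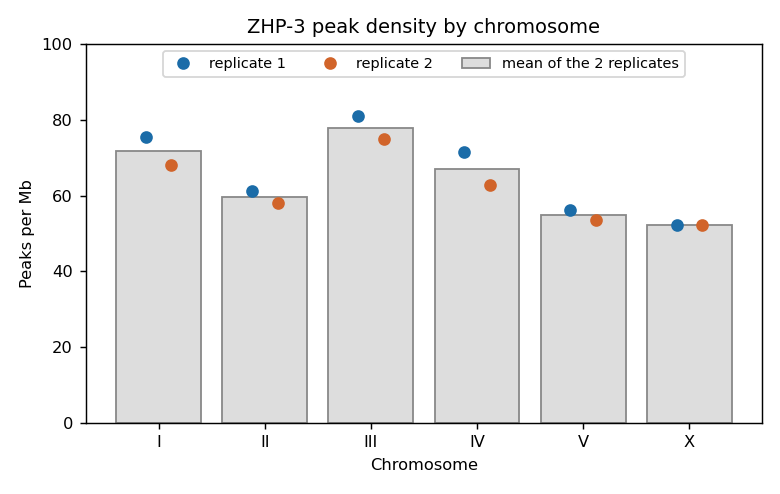
Peaks per Mb (y axis) on each nuclear chromosome (x axis). Bars are the mean of the 2 ChIP replicates and points the replicates themselves; III is highest at a mean of 77.9 and X lowest at 52.1 peaks per Mb.

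Hermaphrodites carry the X in the same copy number as the autosomes. The X held 14.1% of replicate 1 peaks (95% exact interval 13.3% to 15%) and 15.2% of replicate 2 peaks (14.3% to 16.11%), but 17.7% of the sequence. The ratio of X to autosome density was 0.767 in replicate 1 and 0.834 in replicate 2, a mean of 0.80 ± 0.047 (SD, n = 2). It was 0.739 in the combined list. These intervals take peaks as independent, and peaks cluster. In a test added after the data were seen, peaks were shifted along the joined chromosomes, which keeps the clustering. The X deficit then had a permutation p of 0.057 in replicate 1 and 0.171 in replicate 2, with adjusted values of 0.342 and 0.512 over 12 tests. The excess on chromosome III had a permutation p of 0.120 in replicate 1 and 0.011 in replicate 2, with adjusted values of 0.480 and 0.132. No chromosome passed this test after adjustment. Its power was not simulated. The X makes up 17.7% of the joined sequence, so few shifted positions are independent of each other, and a real difference could be missed. Not passing therefore does not show equal density. In the combined list the X test gave an unadjusted permutation p of 0.013, the lowest among its chromosomes, and the III test 0.221. No adjustment was made for that list.

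Meiotic crossovers in this species fall mainly on chromosome arms, and the last comparison set arms against centres. Replicate 1 had 68.3 peaks per Mb on arms and 58.9 in centres, a ratio of 1.16 (95% range of shifts 1.04 to 1.299, permutation p = 0.012). Replicate 2 had 62.2 on arms and 57.6 in centres, a ratio of 1.08 (0.993 to 1.17, permutation p = 0.062), which did not pass; at the clustering of these peaks, 52% of simulations with a true ratio of 1.1 passed. The mean ratio was 1.12 ± 0.057 (SD, n = 2). The combined list gave 1.17 (1.05 to 1.308, permutation p = 0.004), with 124 and 106 peaks per Mb. Regions found in both replicates gave 1.098 (1.005 to 1.2, permutation p = 0.043).

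Chromosome by chromosome, arms were denser than centres in 6 of 6 chromosomes in replicate 1 and in 5 of 6 in replicate 2, the exception being chromosome III at 0.937. None of the 12 single-chromosome ratios passed the permutation test, with the lowest adjusted p at 0.556. The X had ratios of 1.22 and 1.18. On chromosome IV the left arm in replicate 1 held 80.6 peaks per Mb against 63.97 in the centre, and in replicate 2 it held 66.0 against 58.8. The right arm was the densest of the 3 parts in both replicates on II (70.3 and 67.1 peaks per Mb), V (65.1 and 59.1) and X (60.1 and 58.1), and the left arm on I and IV. On II the left arm of replicate 2, at 52.8, was below the centre, at 53.99. On III the left arm was densest in replicate 1 and the centre in replicate 2.

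**Figure D3:**
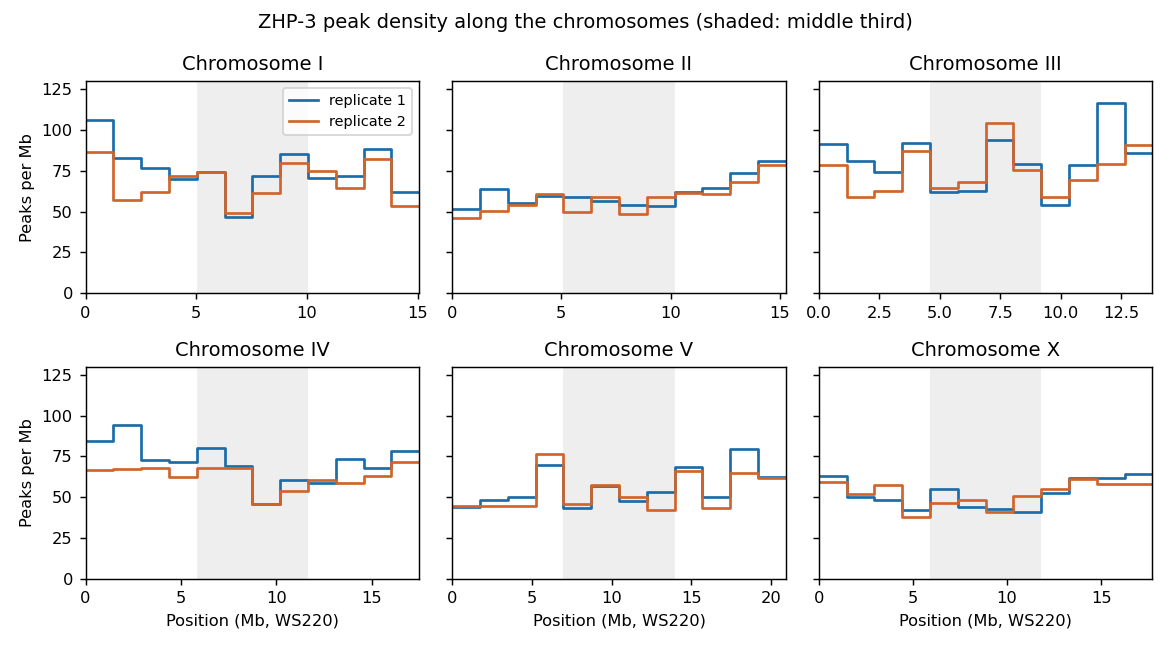
Peaks per Mb (y axis) in 12 equal bins along each nuclear chromosome (x axis, position in Mb on WS220) for the 2 ChIP replicates. The shaded part is the centre; over its 3 parts, chromosome III held 74.4 to 84.7 peaks per Mb in replicate 1, and the X 45.5 to 60.1.

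In the combined list, the arm excess depended on the score of the peaks. In the higher-scoring 50% of the combined list the ratio was 1.06 (0.986 to 1.14, permutation p = 0.108), and in the lower-scoring 50% it was 1.3 (1.09 to 1.56, permutation p = 0.001, the smallest possible). A permutation test of the difference between these sets, shifting scores along each chromosome, gave p = 0.010. In the replicates, ratios of the higher-scoring and lower-scoring peaks were 1.12 and 1.2 in replicate 1, and 1.01 and 1.15 in replicate 2. These differences did not pass the same permutation test (p = 0.431 and 0.090). The lower-scoring sets were chosen for comparison after the data were seen.

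**Figure D4:**
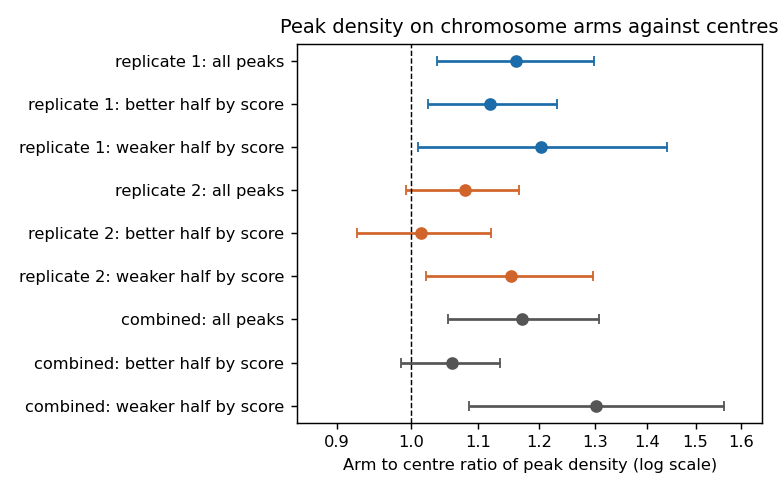
Arm to centre ratio of peak density (x axis, log scale) for each list and for its higher-scoring (better) and lower-scoring (weaker) 50% by the authors' score (y axis). Points are the observed ratios and bars the 95% range of 1000 circular shifts centred on them; the dashed line is equal density, and the lower-scoring 50% of the combined list is highest at 1.3.

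Wide regions, examined after the data were seen, were few. Of the 4634 regions found in both replicates, 35 (0.755%) were wider than 5000 bp and together held 7.59% of the bases of these regions. As merged intervals, they include bases that only 1 replicate called. Chromosome III carried 10 of them and the X 7. The widest was on the X at 4032549 to 4053540 (20.99 kb), built from 6 replicate 1 peaks and 3 replicate 2 peaks. The next spanned 13.8 kb on chromosome I (10205455 to 10219289), with scores of 3100 in both replicates. An 11.1 kb region close to the right end of chromosome I (15060210 to 15071355) was a single peak in every list, also at 3100 in both replicates. The ribosomal RNA gene array lies at this end of chromosome I. Whether repeated sequence gave rise to any of the wide regions was not tested, because the input libraries were not analysed here.

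**Figure D5:**
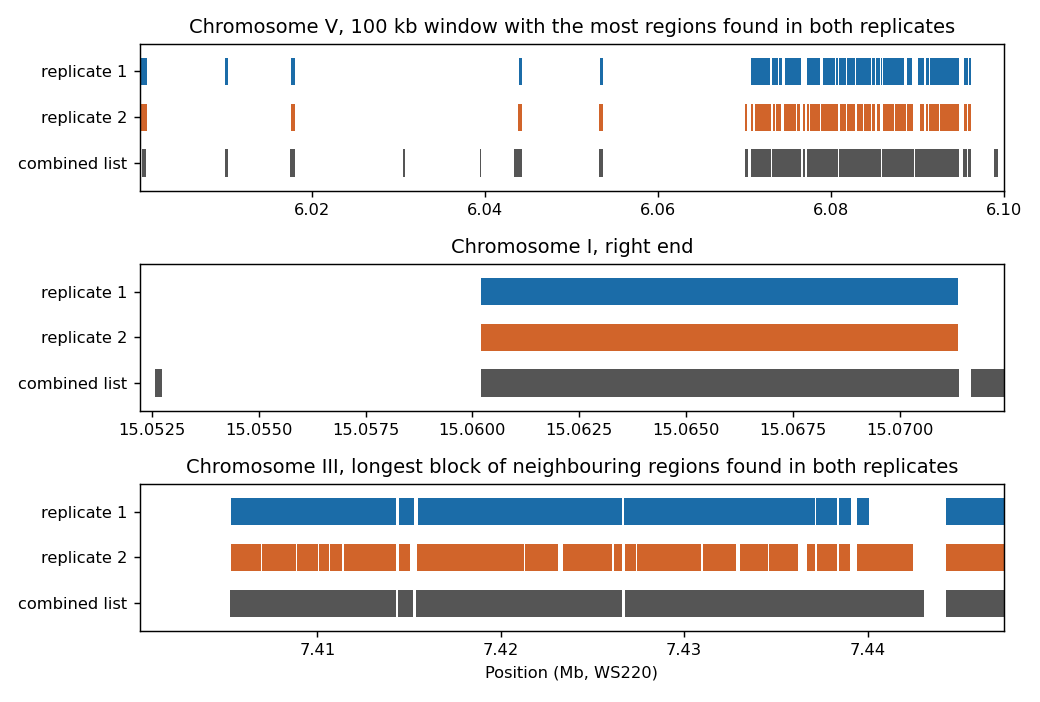
Peaks of the 2 ChIP replicates and of the combined list (rows; boxes are single peaks to scale) against position (x axis, Mb on WS220) in 3 windows. The 11.1 kb peak near the right end of chromosome I is a single box in each row, while the blocks on V and III, windows chosen after the data were seen, consist of many neighbouring peaks.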

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

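All tests of explanations in this part were chosen after the result was seen, except the distance of the combined-list peaks to replicate peaks, whose bound was set beforehand.

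The mitochondrial genome, which was left out of the densities and the arm tests, carried peaks in the combined list alone. A pair of peaks (1 to 13267 and 13458 to 13817) covered 98.6% of its bases, with scores at the 74.9 and 77.5 percentiles of that list. The length used for this share is the last base of the second peak, so coverage of the right end was fixed by definition. Neither replicate list had a mitochondrial peak, so these 2 are counted among the 4919 combined peaks in neither replicate, of which 4917 are nuclear.

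A large part of the combined list, 4919 peaks, was in neither replicate. Their median score was 5.1, against 31.74 for peaks found in both, and their median score percentile was 23.8. This follows from the fall of overlap with score, so a more lenient cut-off in the combined list stays open. From their lowest values, 50.04 and 50.02 against 1.3, the scores may be a scaled −log10 p in the replicates and a −log10 q in the combined list, which the files do not state; limits on p and on q cannot be ranked against each other. Cutting of the same regions into other peaks would place most of them beside replicate peaks, yet 17.9% lay within 500 bp of one, above the 12.3% of circular shifts (permutation p = 0.001, the smallest possible) but far under the 50% set as the bound. No biological explanation was tested.

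The arm excess grew towards weak peaks: the lower-scoring 50% exceeded the higher-scoring 50% of the combined list by a factor of 1.23 in its arm to centre ratio (permutation p = 0.010), and the peaks in neither replicate had a ratio of 1.26. The factors in the replicates, 1.07 and 1.14, did not pass. These values are the pattern itself, so they do not test whether a lenient score threshold added background calls on arms, which stays open. ZHP-3 on crossover-prone arms also stays open. The higher-scoring 50% had a ratio of 1.12 in replicate 1 (permutation p = 0.011) and 1.01 in replicate 2 (permutation p = 0.791). A pass in both replicates, predicted if ZHP-3 sits on such arms, was therefore not met. Ranges at or below 1 in both replicates, predicted if it does not, were not found either. The range of replicate 2, 0.926 to 1.12, barely includes the ratio of replicate 1, which has its own range of 1.02 to 1.23. GC content and repeats, which may also differ between arms and centres, were not tested, because no WS220 sequence was used here.

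All 6 nuclear chromosomes had a peak starting at base 1 in each of the 3 lists, although peaks cover 3.34% to 5.80% of the nuclear bases. These peaks were 210 to 529 bp long, with median score percentiles of 80.3, 92.9 and 89.9 in replicate 1, replicate 2 and the combined list. Reads of repeated end sequence piling on the first bases could give peaks at 6 of 6 left ends, and so could ZHP-3 at chromosome ends. These cannot be told apart from peak positions, because the input libraries were not analysed here. Right ends were not examined, since chromosome lengths were themselves taken from the last peaks.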

How the results depend on the processing

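No paired analysis was possible because the input samples, which share replicate numbers with the ChIP samples, entered no comparison, and the ChIP samples form 1 group. No alternative reversed a direction, but some could hardly have changed a result. With 2 replicates, a value without 1 of them always lies within 1 SD of the mean, and random placement changes the chance level alone. The arm to centre ratio on the X alone was 1.22 in replicate 1 and did not pass (permutation p = 0.315); it rests on fewer peaks than the whole genome. In replicate 2 the lower-scoring 50% of the peaks, an alternative added after seeing the data, gave a ratio of 1.15 that passed (permutation p = 0.021), while the outer parts of 4 as arms gave 1.03 and the higher-scoring 50% gave 1.01. Covered bases gave 1.05 in replicate 2 (permutation p = 0.436) and autosomes alone 1.06 (permutation p = 0.128). In replicate 1 covered bases gave 1.12 (permutation p = 0.036) and autosomes alone 1.15 (permutation p = 0.026). The mean ratio of 1.12 moved to 1.26 in the combined-list peaks found in neither replicate, also an added alternative. The mean X to autosome ratio of 0.80 moved to 0.739 in the combined list; the cause was not tested. Leaving out a replicate gave X to autosome ratios of 0.767 to 0.834 and arm to centre ratios of 1.08 to 1.16; with replicate 2 alone, the test over all peaks was not passed (permutation p = 0.062). A 50% reciprocal overlap lowered the overlap to 66.4% of replicate 1 and 71.3% of replicate 2 peaks. In the higher-scoring 50% of the combined list, 71.3% of peaks were in both replicates against 37.7% in the whole list. Overlaps have no value without either replicate. The start site and gene list alternatives were not run, because no WS220 annotation was used here. The unknown depth of the libraries limits any reading of peaks present in 1 replicate only.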

Other observations

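All values in this part were chosen after the data were seen. Regions found in both replicates were bunched. Of the regions found in both replicates, 27.4% had another within 1000 bp, against 14.9% after random placement (95% range 13.6% to 16.3%, one-sided permutation p = 0.001, the smallest possible). Of the single peaks, 38.1% in replicate 1 and 37.0% in replicate 2 had such a neighbour, against 18.7% and 17.3%. Joining neighbours under 1000 bp apart gave 16 blocks of 10 kb or more, 4 of them on chromosome III and 264.6 kb in all. The longest spanned 37.1 kb on III (7405312 to 7442454), with 97.4% of its bases inside shared regions. It was cut into 12 peaks in replicate 1 and 27 in replicate 2. Next came 25.4 kb on V (6070712 to 6096144), with 25 shared regions, 24.0 kb on X (4032549 to 4056522) and 18.8 kb on IV (6710177 to 6728946). A block of 14.6 kb on V (17117710 to 17132327) had a median score of 3100 in both replicates. Without input, blocks of ZHP-3 cannot be told apart from reads piling on repeated sequence.

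Across 1005 windows of 100 kb, the median was 4 shared regions and 43 windows had none. The window on V from 6.0 to 6.1 Mb, which contains the V block, had 29 and the next, on IV from 6.6 to 6.7 Mb, had 17. Counts of the replicates had a Spearman correlation of 0.82 across windows, which are not independent replicates.

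The X chromosome has its pairing centre, the site that aligns homologues in early meiosis, near its left end. A hypothesis that ZHP-3 peaks are concentrated there predicted more peaks in the leftmost of 10 equal parts of the X than in the rightmost. Replicate 1 had 111 and 114 peaks, a ratio of 0.974 (95% range of circular shifts 0.670 to 1.42, permutation p = 0.913, two-sided). Replicate 2 had a ratio of 1.02 (0.686 to 1.48, permutation p = 0.899). The mean ratio was 0.997. No excess of the left end over the right end was detected, and the ranges leave room for one. The left end was not tested against the rest of the X. Peak number does not measure the strength of the signal.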
